A study of Mus musculus with 36 samples.

How the data were processed

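Liver RNA of 36 mice was hybridised by the authors to Affymetrix whole-transcript mouse arrays of the exon-level kind, 1 array per library. Per the labels, the animals were female C57BL/6 mice lacking dermatopontin (Dpt) or their wild-type littermates, aged 10 to 12 weeks. Carbon tetrachloride (CCl4) was injected under the skin 3 times a week at 0.1 ml/kg for 8 weeks, and control animals received olive oil. The solution held 2% CCl4 in the first week, 4% in the second, 5% in the third, 6% in the fourth and 8% in weeks 5 to 8. Livers were taken 24 hours after the last injection. The labels give 8 wild-type (WT) and 10 knockout (KO) libraries after oil, and 9 WT and 9 KO libraries after CCl4. Groups were taken from these labels alone, and no library was moved to another group.

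The deposited values are log2 probe set signals that the authors made with RMA (background correction, quantile normalization between arrays and median polish). The software version, probe set definition and genome build are not given in the sources used here. The table holds 269479 probe sets. Values ran from 0.78 to 13.66 and array medians over genes from 4.11 to 4.38. Another deposited table of normalized values has 36 columns whose names match no sample, so it was not used here. Its 272 extra probe sets include 190 control probe sets. No 2 arrays held identical values (0 pairs), and the highest correlation of 2 arrays across genes was 0.9888.

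Probe sets were joined to genes through the platform's own annotation. Of the probe sets, 233753 name 1 gene symbol and were kept, 5139 name several and 30587 name none, and these were left out. Symbols were brought up to date for 2189 genes with a table of mouse genes on assembly GRCm38.p6, which was also used to tell which genes lie near Dpt. The mean of a gene's probe sets was its value, which gave 23152 genes with a median of 8 probe sets each (highest 272). A single probe set stands for 2319 genes. No filter on low values was applied. Arrays have no read depth, and their number limits the precision.

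A linear model with 1 mean per group was fitted to all 36 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes variances. The 5 contrasts were CCl4 against oil in WT, CCl4 against oil in KO, KO against WT after oil, KO against WT after CCl4, and the interaction, which is the CCl4 effect in KO minus that in WT. A gene was called, and is said to have risen or fallen, when its Benjamini-Hochberg adjusted p over all genes of a contrast was under 0.05. Tests are two-sided unless stated. Errors given with a log2 fold change are its standard error from limma.

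A total of 37 lists of genes (cell types, pathways and tissues other than liver) were fixed before the data were examined, as were the groups, contrasts, tests, thresholds, the rule for named genes and the first set of alternatives below. Of these lists, 36 had at least 5 measured members. The erythroid list had fewer and was not tested. Each list was compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Members were also adjusted over the list alone. A list's score in a library is the mean log2 value of its members. Scores of KO and WT were compared by an exact permutation test over 48620 splits of the CCl4 libraries and 43758 splits of the oil libraries, and their interaction by 100000 permutations, each adjusted over the lists. Genes called between genotypes within 10 Mb of Dpt were counted against all other genes by a one-sided Fisher exact test, with windows of 5 Mb and 20 Mb as alternatives. Correlations of log2 fold changes are across genes, and genes are not independent replicates. Their standard error comes from a jackknife over libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the permutation and Fisher tests and the tables.

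The genes named are Dpt, the 10 largest called rises and falls of each contrast, up to 4 called members of each list by size of change, up to 2 members with the smallest adjusted p of a list with none, and up to 10 called genes near Dpt. Provisional symbols, small RNA genes and immunoglobulin or T cell receptor segments were left out of the largest changes. Counts of 5 or fewer genes are given by name where a gene stands for a count.

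The steps were tested on simulated data with 200 changed genes per contrast. Normal noise with each gene's residual SD in these arrays was drawn independently for each gene and library. At a fold of 2, between 91% and 94% of the changed genes were recovered. At a fold of 1.5, 70% to 75% were recovered in the 4 contrasts of groups and 37% in the interaction, and 2.4% to 5.8% of calls were false. A simulated list was called in every contrast, with 0 of the other lists. The simulated noise was independent between genes, so this cannot test the camera p-values of lists whose genes are correlated. The permutation test passed 4% of 200 simulated scores without a difference and 97.5% of those with a difference of 2 SD.

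The first set of alternatives was the probe set with the highest mean per gene, cyclic loess between arrays, arrays centred on their median, genes at or above the median level only, a variance trend with robust estimates, array weights, the number in the title as a block, a fold change of at least 1.5 as a further condition, only the groups of a contrast in the fit, medians and z scores for list scores, Spearman correlation, and leaving out each library in turn. A further 7 alternatives were added after seeing the data. They leave out the 2 libraries whose Dpt goes against their label, the 6 libraries that express Y-linked genes, the 2 libraries with low hepatocyte genes, the 7 libraries with markers of other tissues, the first and the last of these sets together (8 libraries), or the first 3 together (10 libraries), or they add Y-linked expression as a term. Low hepatocyte genes means a periportal score over 1.5 log2 below the median of all arrays. Markers of other tissues means an adipocyte, pancreatic or muscle score over 1 log2 above that median.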

Results

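Expression was measured in livers of mice lacking dermatopontin (Dpt), a small protein of the extracellular matrix that binds decorin and collagen fibrils, and of their wild-type littermates. Both were given CCl4, a solvent that hepatocytes turn into a toxic radical and that scars the liver on repeated dosing, or olive oil alone. The 36 arrays comprise 8 WT and 10 KO libraries after oil, and 9 WT and 9 KO libraries after CCl4. Each gives log2 signals for 23152 genes, and array medians over genes lay between 4.11 and 4.38. The number of arrays limits the precision.

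Dpt itself was read first, as a check of the labels. Averaged over its 5 probe sets, Dpt lay between 5.59 and 6.48 in the 8 libraries labelled WT after oil, and between 3.00 and 3.87 in 18 of the 19 libraries labelled KO. The library labelled KO_control 10 read 7.40. The library labelled WT_CCl4 1 read 3.18, against 7.48 to 10.12 in the other 8 libraries of its group. The arrays give no zero level for a gene, so these values do not say how much Dpt RNA remains in KO. They lay close to Xist in the 6 libraries that express Y-linked genes (2.94 to 4.45) and to Y-linked genes in the others (2.34 to 3.06). Log2 differences of Dpt between KO and WT may thus be limited by background. Groups are named by label throughout, so every direction between groups rests on labels that these 2 libraries go against. After CCl4, Dpt fell by 4.38 ± 0.53 in KO relative to WT (log2 fold change ± SE, 9 against 9 libraries, adjusted p = 1.9e-05, lower in 9 of 9). After oil it was lower in 9 of 10 KO libraries, but the difference of -2.06 ± 0.53 (10 against 8) did not pass the test over all genes (adjusted p = 0.655). Without both libraries it was -2.45 (adjusted p = 9.27e-09). In WT, Dpt rose by 1.91 ± 0.55 with CCl4 in 8 of 9 libraries (adjusted p = 0.0102). Without the 7 libraries that carry markers of other tissues this rise was 0.90 and was not called (adjusted p = 0.236), with WT_CCl4 1 as 1 of the 4 WT libraries left after CCl4. With WT_CCl4 1 left out as well it was 2.13 and was called (adjusted p = 2.74e-10). In KO the CCl4 difference was -0.41 ± 0.52 (9 against 10, adjusted p = 0.622), and -0.02 without the 2 libraries (adjusted p = 0.961). The interaction of Dpt was -2.32 ± 0.75 (adjusted p = 0.848), and -2.52 without the 2 libraries (adjusted p = 2.79e-05). With KO values close to background under both treatments, the interaction may largely restate the rise in WT.

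**Figure D1:**
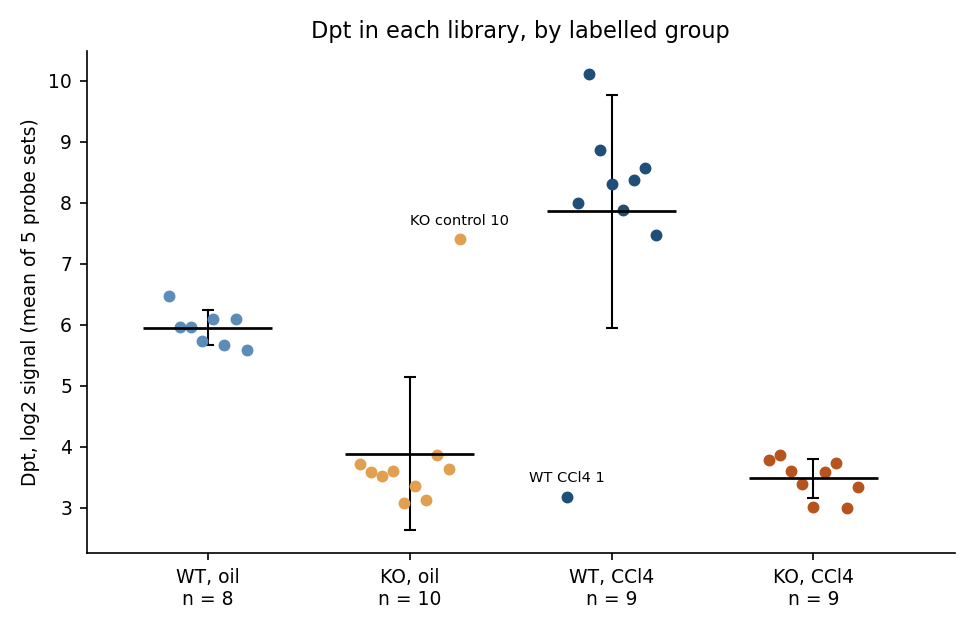
Dpt (log2 signal, mean of 5 probe sets) in each of the 36 libraries by labelled group, 1 point per library with the group mean and SD. The library labelled KO_control 10 lies at 7.40 above 3.07 to 3.87 in the rest of its group, and the library labelled WT_CCl4 1 lies at 3.18 below 7.48 to 10.12.

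Other transcripts also separated libraries within groups. Pancreatic, muscle or adipocyte markers stood more than 1 log2 above the median of all arrays in 7 libraries, those labelled KO_control 10, WT_CCl4 3, 4, 5, 8 and 9, and KO_CCl4 5. These are 5 of the 9 WT libraries after CCl4 and 1 of the 9 KO libraries. Pancreatic markers such as Cpb1 and Prss2 averaged 10.83 in WT_CCl4 4 against 3.29 to 6.61 in the rest of its group. Periportal hepatocyte genes were low in WT_CCl4 3 (5.97, others 8.02 to 8.86) and in KO_CCl4 5 (5.78, others 8.24 to 8.84). Of the oil libraries, all labelled female, 6 (WT_control 1, 2 and 3, and KO_control 1, 3 and 4) expressed Y-linked genes at a mean of 6.09 to 6.4, against 2.34 to 3.06 in the other 30 libraries. Xist, which is made from an inactive X chromosome, was 2.94 to 4.45 in those 6 and 9.29 to 10.29 in the others. No CCl4 library expressed Y-linked genes (0 of 18), so sex-biased transcripts move with the treatment comparisons.

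**Figure D2:**
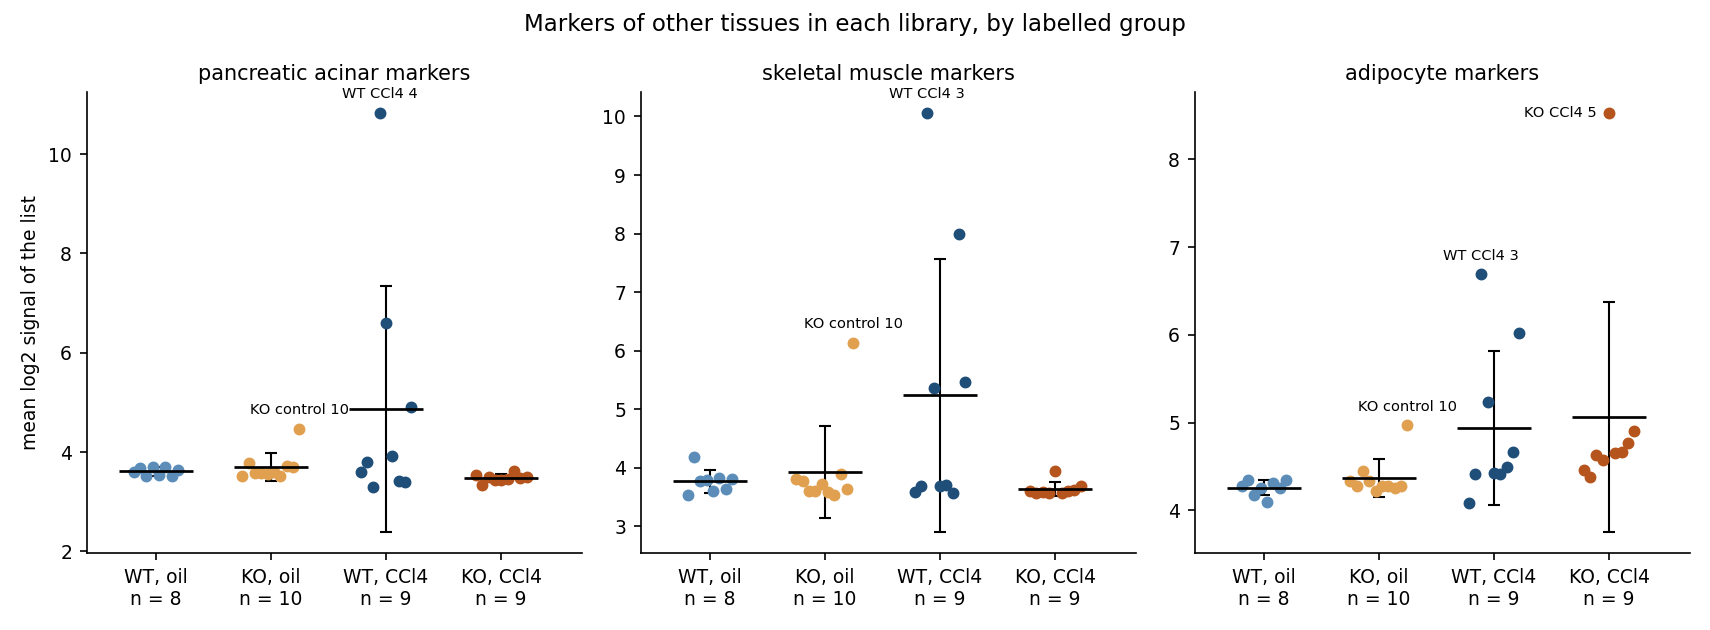
Mean log2 signal of pancreatic acinar, skeletal muscle and adipocyte marker lists in each library by labelled group, 1 point per library with the group mean and SD. The highest pancreatic score is 10.83 in the library labelled WT_CCl4 4, the highest muscle score 10.06 in WT_CCl4 3 and the highest adipocyte score 8.53 in KO_CCl4 5.

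The comparison of CCl4 with oil in WT asked how a liver with Dpt responds to repeated injury. Genes of scar matrix rose together. The chains of type I collagen, Col1a1 and Col1a2, rose by 3.20 ± 0.36 and 2.65 ± 0.31, and type III collagen Col3a1 by 2.43 ± 0.35 (log2, ± SE, 9 against 8 libraries, each higher in 9 of 9, highest adjusted p = 1.37e-05). Of 28 measured genes of fibrillar and basement membrane matrix, 24 rose, 0 fell and 4 were not called, with 26 rising when adjusted over the list alone (median 1.2). Thbs1, an activator of latent TGF-beta, rose by 2.65 ± 0.43. Lum rose by 2.16 ± 0.28, Bgn by 0.99 ± 0.15 and Dcn, the proteoglycan that Dpt binds, by 1.00 ± 0.20. These belong to 12 measured small leucine-rich proteoglycans, of which 6 rose and 0 fell (6 adjusted over the list alone, median 0.57). Their score was 6.76 in WT_CCl4 3, which carries muscle markers, and next highest at 5.66 in WT_CCl4 8. Without the 10 libraries that go against their labels, have low hepatocyte genes or express Y-linked genes, 5 rose and the median was 0.39. Of 8 described Dpt binding partners, 7 rose (8 adjusted over the list alone, median 0.84).

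Enzymes that shape collagen rose as well. Lox and Loxl1, which crosslink fibrils, rose by 2.30 ± 0.28 and 2.21 ± 0.33, Plod2 by 1.97 ± 0.29 and Crtap by 1.51 ± 0.22. Of 17 crosslinking genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.99). Among 17 matrix proteases and inhibitors 14 rose (14 adjusted over the list alone, median 1.02), with Mmp2 at 2.43 ± 0.37, Plat at 2.43 ± 0.30 and Timp1 at 2.08 ± 0.31. The macrophage elastase Mmp12 rose by 3.66 ± 0.39 over its mean of 18 probe sets, but its single highest probe set gave -0.06. Of 17 genes of TGF-beta signalling 14 rose (14 adjusted over the list alone, median 0.76), among them Ccn2 at 1.15 ± 0.23 and Tgfbr2 at 1.04 ± 0.19. Of 20 markers of stellate cells, the liver's main matrix producers, and of the myofibroblasts they form, 12 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.99). Acta2 rose by 2.45 ± 0.30, Des by 2.13 ± 0.49 and Pdgfra by 1.86 ± 0.32. With each library left out in turn, Des ranged from 1.63 to 2.37 and Acta2 from 2.37 to 2.61. Libraries of this group carry muscle markers (scores of 10.06 in WT_CCl4 3 and 8.00 in WT_CCl4 8), so Des cannot be read as stellate cells alone.

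Most macrophage markers and some markers of neutrophils, B and plasma cells, ducts and vascular endothelium rose in WT. Gpnmb, made by lipid-laden macrophages, rose by 4.54 ± 0.50, Itgam by 2.58 ± 0.46, Cd68 by 1.87 ± 0.32 and Itgax by 1.77 ± 0.30. Of 21 monocyte and macrophage markers 16 rose and 0 fell (21 adjusted over the list alone, median 1.02). Of 12 neutrophil markers 5 rose (5 adjusted over the list alone, median 0.39), and of 11 B and plasma cell markers 5 rose (7 adjusted over the list alone, median 0.86). The B and plasma cell score was 7.61 in WT_CCl4 3 and next highest in WT_CCl4 4, which carry muscle and pancreatic markers, against at most 5.09 in the other 7 libraries of the group. Without the 10 libraries that go against their labels, have low hepatocyte genes or express Y-linked genes, the medians were 0.53 for B and plasma cell and 0.24 for neutrophil markers. Spp1 rose by 1.67 ± 0.28 and Bicc1 by 1.74 ± 0.26, within 12 duct markers of which 6 rose (7 adjusted over the list alone, median 0.51). Cd34 rose by 1.82 ± 0.42 and Ednrb by 1.25 ± 0.21, within 11 vascular endothelial markers of which 6 rose (9 adjusted over the list alone, median 0.49). Among 24 cell cycle genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.46), and the replication helicase genes Mcm6 and Mcm2 rose by 1.61 ± 0.26 and 1.35 ± 0.24. The epithelial genes Sprr1a and Ly6d rose by 5.57 ± 0.69 and 3.88 ± 0.50.

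Many hepatocyte genes fell in WT, though not every list of hepatocyte genes fell as a whole. Slco1a1, an uptake carrier of bile acids, fell by 5.46 ± 0.69, and Cyp7b1 and Cyp8b1 fell by 2.45 ± 0.51 and 1.94 ± 0.41. Of the WT libraries 3 of 8 after oil and 0 of 9 after CCl4 express Y-linked genes. Part of a fall in sex-biased genes may come from that imbalance. Of 17 bile acid genes 10 fell and 1 rose (12 and 1 adjusted over the list alone, median -1.5). Genes of pericentral hepatocytes, which activate CCl4, fell in 14 of 18 (15 adjusted over the list alone, median -1.46), with Slc1a2 at -3.16 ± 0.41, Cyp1a2 at -2.20 ± 0.55 and Lhpp at -1.83 ± 0.26. Periportal genes fell in 6 of 17 (7 adjusted over the list alone, median -0.64), Asl by -1.25 ± 0.34. The periportal score of WT_CCl4 3 lies far below its group, and the median was -0.48 without the 10 libraries, of which it is 1. Lipogenic genes fell in 13 of 20 and rose in 1 (13 and 2 adjusted over the list alone, median -0.69), with Thrsp at -1.78 ± 0.39 and Mlxipl at -1.47 ± 0.24, while Cidec rose by 2.12 ± 0.58. Cholesterol synthesis genes fell in 12 of 20 (13 adjusted over the list alone, median -0.73), including Tm7sf2 at -1.52 ± 0.29 and Pmvk at -1.14 ± 0.20. Pdk4 and Acot2 rose by 2.40 ± 0.33 and 2.17 ± 0.34, but 23 genes of fatty acid oxidation split into 3 up and 2 down (3 and 2 adjusted over the list alone, median -0.01, mean 0.09). Genes driven by growth hormone pulses fell in 11 of 15 (12 adjusted over the list alone, median -1.77), Elovl3 by -4.40 ± 0.86 and Hsd3b5 by -3.45 ± 0.80. Of 25 xenobiotic enzymes 8 fell (8 adjusted over the list alone, median -0.78), and 16 fell and 1 rose without the 10 libraries.

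In all, 5666 genes were called in WT, 3048 up and 2618 down (2358 up and 5380 down with arrays centred on their medians), and 8676 had an unadjusted p under 0.05. By camera, the matrix list gave an adjusted p = 6.68e-22, matrix proteases 2.71e-12, crosslinking 2.9e-10, TGF-beta 5.4e-10, binding partners 1.42e-08, stellate markers 7.75e-07 and duct markers 4.04e-06, each with adjusted p = 0.061 with an estimated correlation. Macrophage markers gave 1.5e-14 (adjusted p = 0.106 with an estimated correlation), pericentral genes 1.42e-08 (adjusted p = 0.15 with an estimated correlation) and growth hormone targets 6.57e-06 (adjusted p = 0.0819 with an estimated correlation). Without the 6 Y-expressing libraries, Elovl3 was -2.98, Hsd3b5 -1.94 and Cyp2d9 -2.05 in place of -3.24, all still called, and 3403 genes were called. Without the 7 libraries with other tissue markers 3391 were called. These markers moved with the comparison: of 12 pancreatic genes 1 rose (0 adjusted over the list alone, median 1.17), of 8 muscle genes 2 rose (8 adjusted over the list alone, median 1.41), of 8 adipocyte genes 2 rose (2 adjusted over the list alone) and of 7 mesothelial genes 3 rose (6 adjusted over the list alone). The muscle gene Myh1 rose by 2.04 ± 0.74 in 6 of 9 libraries and was -0.07 without those libraries.

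The same comparison in KO asked how a liver without Dpt responds. Collagen genes rose in KO as well, Col1a1 by 3.53 ± 0.34, Col1a2 by 2.91 ± 0.30 and Col3a1 by 2.69 ± 0.33 (9 against 10 libraries, each higher in 9 of 9, highest adjusted p = 4.57e-07). Of the 28 matrix genes 27 rose and 1 was not called (27 adjusted over the list alone, median 1.28). Lum rose by 2.39 ± 0.27, Bgn by 1.03 ± 0.14 and Dcn by 1.00 ± 0.19, and 6 of 12 small proteoglycans rose (6 up and 1 down adjusted over the list alone, median 0.48). The proteoglycan score was highest in KO_CCl4 5 at 6.35, and without the 10 libraries 6 rose and the median was 0.36. All 8 binding partners rose (8 adjusted over the list alone, median 1.02), Tgfb1 by 1.16 ± 0.18. Lox rose by 2.50 ± 0.27, Loxl1 by 2.38 ± 0.31 and the collagen chaperone Serpinh1 by 1.71 ± 0.21, within 14 of 17 crosslinking genes (14 adjusted over the list alone, median 0.93). Timp1 rose by 2.45 ± 0.29, Mmp2 by 2.59 ± 0.35 and Plat by 2.44 ± 0.28, within 15 of 17 proteases and inhibitors (16 adjusted over the list alone, median 1.35). Of the TGF-beta genes 14 of 17 rose (14 adjusted over the list alone, median 0.91), Tgfbi by 1.14 ± 0.15. Stellate markers rose in 10 of 20 and fell in 2 (11 and 3 adjusted over the list alone, median 0.54), with Acta2 at 2.32 ± 0.29, Pdgfrb at 1.93 ± 0.23 and Vim at 1.82 ± 0.28.

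All 21 macrophage markers rose in KO (21 adjusted over the list alone, median 1.49), Gpnmb by 4.53 ± 0.47, Itgam by 3.03 ± 0.43, Itgax by 2.94 ± 0.29 and Cd68 by 2.48 ± 0.30. Neutrophil markers rose in 8 of 12 (10 adjusted over the list alone, median 0.84), Csf3r by 1.40 ± 0.21 and S100a8 by 1.53 ± 0.25. Interferon-stimulated genes rose in 9 of 21 (10 adjusted over the list alone, median 0.38), Oasl2 by 1.21 ± 0.22, whereas in WT 3 rose and 3 fell (3 and 3 adjusted over the list alone, median -0.08, mean 0.01). Of the acute phase genes 6 of 21 rose in KO (6 adjusted over the list alone, median 0.31), Lcn2 by 2.87 ± 0.36 and Saa3 by 2.73 ± 0.55. In WT 2 rose (2 adjusted over the list alone, median -0.09, mean 0.06), Lcn2 by 2.25 ± 0.38 and Saa3 by 2.40 ± 0.58. Without the 10 libraries 13 rose and 1 fell in KO (median 0.58) and 7 rose and 2 fell in WT (median 0.15). The list then passed camera with the preset correlation in both (adjusted p = 2.78e-07 and 0.0104), in a fit chosen after seeing the data. Kupffer cell markers, of the resident macrophages, rose in 4 of 10 in KO (4 adjusted over the list alone), Marco by 2.25 ± 0.34, and in WT 1 rose and 1 fell (1 and 1 adjusted over the list alone, median -0.04, mean 0.12). Without the 10 libraries 5 Kupffer cell markers rose and 1 fell in KO, and 3 rose and 1 fell in WT. Duct markers rose in 8 of 12 (9 adjusted over the list alone), Spp1 by 2.07 ± 0.26 and Bicc1 by 1.89 ± 0.25. Vascular endothelial markers rose in 7 of 11 (8 adjusted over the list alone), Cd34 by 1.54 ± 0.40. Cell cycle genes rose in 19 of 24 (21 up and 1 down adjusted over the list alone, median 0.72), Mcm6 by 2.00 ± 0.24 and Mcm5 by 1.81 ± 0.25. B and plasma cell markers rose in 3 of 11 (3 adjusted over the list alone). T and NK cell markers gave 1 rise among 15 in KO, and 2 rises and 1 fall in WT, with the same counts adjusted over the list alone. Sinusoidal endothelial markers gave 1 rise and 1 fall among 14 in KO, and 1 fall in WT (1 rise in KO and 0 changes in WT adjusted over the list alone), with 5 falls in each without the 10 libraries.

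Many hepatocyte genes fell in KO too, where 3 of 10 libraries after oil and 0 of 9 after CCl4 express Y-linked genes. Slco1a1 fell by 5.33 ± 0.65 and Cyp7b1 by 2.11 ± 0.48, with 10 of 17 bile acid genes down and 1 up (11 and 1 adjusted over the list alone, median -1.49). Pericentral genes fell in 14 of 18 (15 adjusted over the list alone, median -1.55), Slc1a2 by -3.39 ± 0.39 and Oat by -1.84 ± 0.26. Periportal genes fell in 5 of 17 and rose in 1 (7 and 1 adjusted over the list alone, median -0.69), Etnppl by -2.28 ± 0.44. Without the 10 libraries, of which KO_CCl4 5 is 1, the median was -0.35. Lipogenic genes fell in 14 of 20 and rose in 1 (14 and 1 adjusted over the list alone), Acacb by -1.5 ± 0.26 and Me1 by -1.40 ± 0.25. Cholesterol synthesis genes fell in 8 of 20 (9 adjusted over the list alone), Stard4 by -1.26 ± 0.21. Fatty acid oxidation genes fell in 6 of 23 and rose in 2 (7 and 2 adjusted over the list alone), with Pdk4 up by 1.49 ± 0.31. Growth hormone targets fell in 9 of 15 (11 adjusted over the list alone), Elovl3 by -4.71 ± 0.82, and xenobiotic enzymes in 7 of 25 (9 adjusted over the list alone), or in 20 with 1 rise without the 10 libraries. Periportal genes then fell in 9. Cyp1a2, at -1.77 ± 0.52, was -1.66 and no longer called without the 6 Y-expressing libraries (adjusted p = 0.0669), nor was Cyp2d9, at -2.47 ± 0.70 and then -1.37 (adjusted p = 0.0894).

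In KO 5389 genes were called, 3100 up and 2289 down (2505 up and 4710 down with centred arrays), and 8074 had an unadjusted p under 0.05. By camera, matrix gave an adjusted p = 3.71e-27, macrophage markers 4.72e-25, proteases 1.85e-15, crosslinking 1.16e-13, TGF-beta 5.53e-11 and duct markers 1.53e-06. These 6 lists passed with an estimated correlation as well (0.0333 each), as did binding partners (0.0335). Cell cycle genes gave 3.88e-12 (adjusted p = 0.0766 with an estimated correlation), pericentral genes 1.66e-09 (adjusted p = 0.0949 with an estimated correlation) and interferon-stimulated genes 6.82e-05 (adjusted p = 0.195 with an estimated correlation). No pancreatic or muscle marker was called in KO (0 of 12 and 0 of 8). Of the adipocyte markers 2 of 8 rose (2 adjusted over the list alone, median 0.68, and 0.16 without the 10 libraries). Mesothelial markers rose in 6 of 7 (7 adjusted over the list alone, median 1.16). Of 9 intestinal markers 1 fell in each genotype (1 each adjusted over the list alone).

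**Figure D3:**
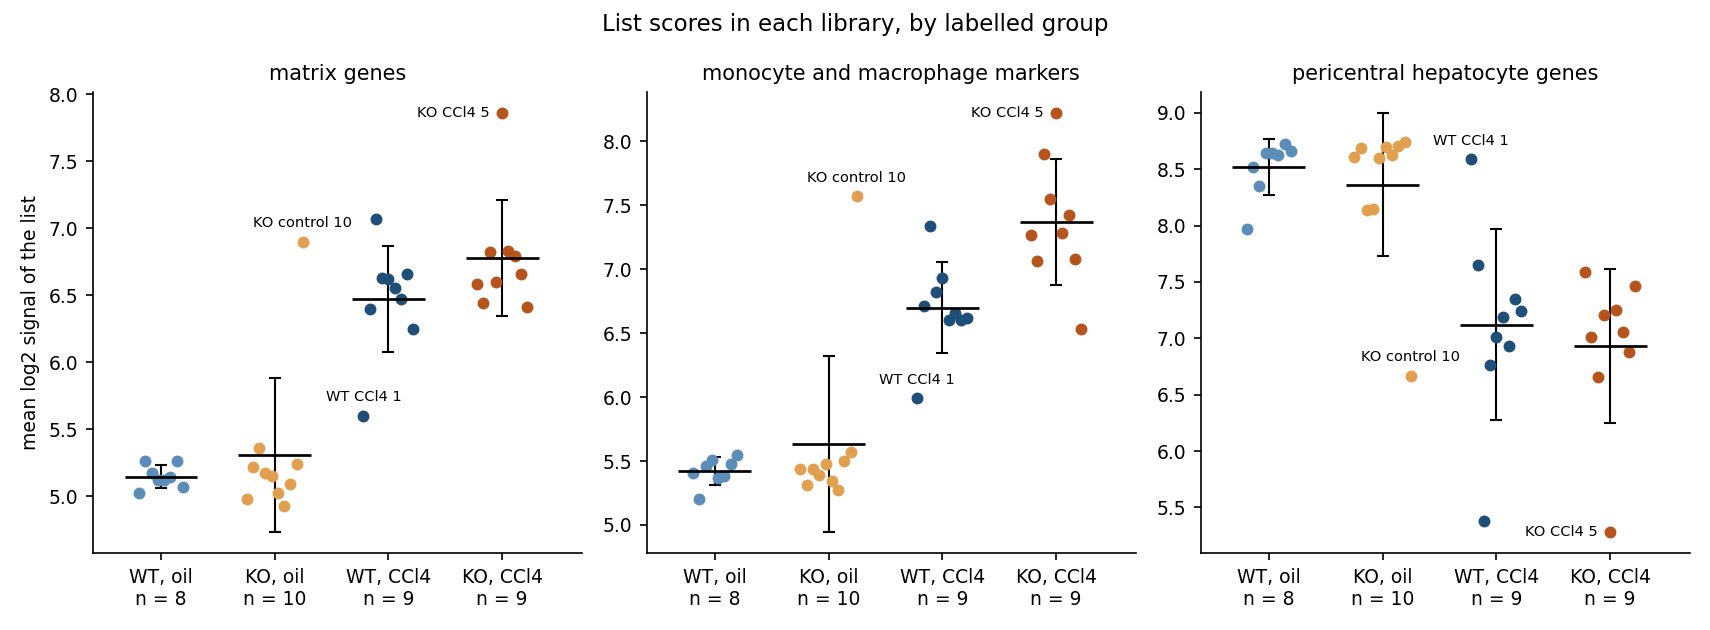
Mean log2 signal of the matrix, macrophage and pericentral hepatocyte lists in each library by labelled group, 1 point per library with the group mean and SD. The matrix score averages 5.14 in WT and 5.31 in KO after oil, and 6.47 and 6.78 after CCl4.

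Targets of p53 rose in both genotypes. Among them Cdkn1a, which halts the cell cycle, rose by 2.18 ± 0.24 in WT and 1.65 ± 0.23 in KO. Of 15 p53 targets 10 rose in WT and 7 in KO (11 and 9 adjusted over the list alone, medians 0.63 and 0.53), and this list passed camera in both (adjusted p = 1.42e-08 and 1.28e-05) and with an estimated correlation (0.0486 and 0.0436). Atf3 rose by 2.00 ± 0.26 and 1.87 ± 0.25 and Ddit3 by 1.28 ± 0.18 and 1.17 ± 0.17, among 15 genes of the unfolded protein response of which 8 rose in each genotype, while 1 fell in KO (8 up and 1 down, and 8 up and 2 down, adjusted over the list alone, medians 0.81 and 0.69). That list gave a camera adjusted p = 0.000272 in WT and 0.000602 in KO (adjusted p = 0.204 and 0.201 with an estimated correlation), with medians of 0.92 and 1.06 without the 10 libraries. The glutathione precursor carrier Slc7a11 rose by 1.77 ± 0.28 and 1.39 ± 0.26, and Hmox1 by 1.02 ± 0.25 and 1.66 ± 0.24. Of 19 NRF2 genes 8 rose in WT, and 6 rose and 1 fell in KO (8, and 7 and 1, adjusted over the list alone). The list gave a camera adjusted p = 0.0105 in WT and 0.0549 in KO (adjusted p = 0.359 and 0.448 with an estimated correlation), or 0.000214 and 0.00182 without the 10 libraries, and 0.497 for the interaction. The clock output gene Dbp fell by 1.29 ± 0.24 and 1.64 ± 0.22 and Npas2 rose by 0.91 ± 0.23 and 1.19 ± 0.22. Of 16 clock genes 7 fell and 3 rose in WT, and 9 fell and 2 rose in KO (8 and 3, and 9 and 2, adjusted over the list alone). Oxidative phosphorylation genes fell in 11 of 18 in WT and 13 of 18 in KO (12 and 14 adjusted over the list alone), Ndufa9 by 0.52 ± 0.13 and 0.48 ± 0.12.

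The CCl4 effects of the genotypes were set side by side across genes. Col1a1, Gpnmb, Lox and Acta2 rose and Slco1a1 and Slc1a2 fell in both. Of the called genes, 3371 were called in both genotypes and all 3371 had the same sign, where 667 would be shared with one sign if the lists were independent. The correlation of log2 fold changes across 23152 genes was r = 0.863 (jackknife SE over libraries 0.04). Centring the arrays on their medians moved the median of all genes from -0.043 to -0.134 in WT and from -0.04 to -0.126 in KO. The balance of rises and falls thus rests on the scaling. No called gene named here changed sign with centring or cyclic loess.

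**Figure D4:**
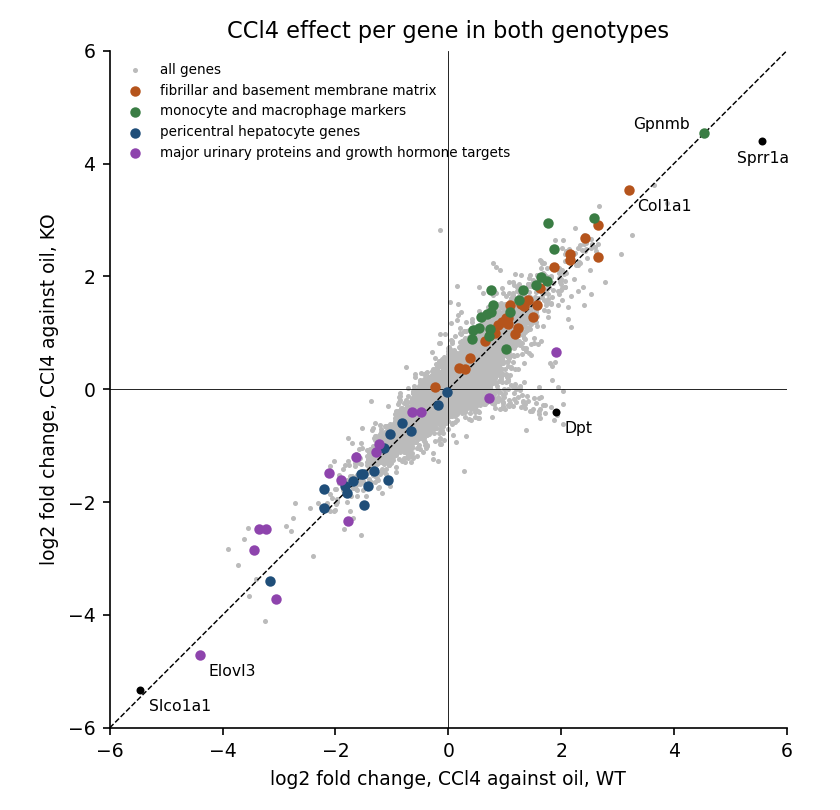
Log2 fold change with CCl4 in WT (x axis) and in KO (y axis), 1 point per gene, with 4 gene lists in colour, all other genes in grey and a dashed line of equal change. Col1a1 lies at 3.20 in WT and 3.53 in KO and Slco1a1 at -5.46 and -5.33, while Dpt lies at 1.91 and -0.41.

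KO against WT after oil asked what loss of Dpt changes in an uninjured liver. Called genes were few and 7 of the 8 lie within 10 Mb of Dpt. Ifi202b, an interferon-induced DNA sensor, rose by 1.55 ± 0.30 (adjusted p = 0.0265) and the pericyte gene Rgs5 by 0.90 ± 0.15 (adjusted p = 0.0035). The phosphatase genes Dusp23 and Dusp12 fell by 1.15 ± 0.16 (adjusted p = 0.000428) and 0.61 ± 0.12 (adjusted p = 0.0402), the noncoding RNA Gas5 by 1.00 ± 0.17 (adjusted p = 0.00561), Cenpl by 0.69 ± 0.11 and Cfap126 by 0.52 ± 0.10. The odorant receptor gene Olfr1269, which has 1 probe set and lies elsewhere, fell by 1.14 ± 0.19. Each was on the same side in 10 of 10 KO libraries relative to the WT mean (10 against 8). A total of 877 genes had an unadjusted p under 0.05. Within 10 Mb of Dpt 7 of 236 genes were called, against 1 of 22824 elsewhere (odds ratio 709, 95% interval 88.9 to 16400, one-sided Fisher exact p = 8.53e-14). Gas5 was 0.01 with its single highest probe set. Without the 6 Y-expressing libraries 1 gene was called.

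No matrix gene was called after oil (0 of 28 by limma, and 0 adjusted over the list alone). Col1a1 differed by 0.31 ± 0.35 and Dcn by 0.12 ± 0.20, within the spread of libraries. By camera the matrix list lay higher in KO (median 0.15, adjusted p = 0.00441, adjusted p = 0.974 with an estimated correlation) and macrophage markers too (median 0.17, adjusted p = 0.00265, adjusted p = 0.974 with an estimated correlation). The library labelled KO_control 10 had a matrix score of 6.90 against 4.93 to 5.36 in the other KO oil libraries. Without the 2 libraries that go against their labels, the matrix list lay lower in KO and was not called (adjusted p = 0.98), as did the macrophage list (adjusted p = 0.98). Matrix scores differed by 0.16 (exact permutation p = 0.724, adjusted p = 0.958, higher in 6 of 10). Oxidative phosphorylation genes lay lower (median -0.15, adjusted p = 0.000548, adjusted p = 0.974 with an estimated correlation), as did cholesterol synthesis genes (median -0.22, adjusted p = 0.00267, adjusted p = 0.974 with an estimated correlation). A further 5 lists lay higher in KO, namely p53 targets (0.00441), proteases and stellate markers (0.0171 each), binding partners (0.0367) and crosslinking genes (0.0406), each with adjusted p = 0.974 with an estimated correlation. None of these 5 was called without the 10 libraries, where the medians were 0 for p53 targets (adjusted p = 0.372), -0.02 for proteases, -0.05 for stellate markers, -0.01 for binding partners and -0.04 for crosslinking genes.

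KO against WT after CCl4 asked whether loss of Dpt alters the injured liver. Besides Dpt, 11 genes were called. Ifi202b rose by 2.36 ± 0.29 (adjusted p = 2.01e-05) and Gas5 fell by 1.23 ± 0.17 (adjusted p = 0.000155), and both were also called after oil. The integrin gene Itgax rose by 1.45 ± 0.29 (adjusted p = 0.0415, 8 of 9 libraries), the Fc receptor chain Fcer1g by 1.12 ± 0.21 and the nucleic acid sensor Zbp1 by 0.80 ± 0.15 (adjusted p = 0.0248 each, 9 of 9), and Gsdmd and Tnfrsf14 by 0.45 ± 0.09 and 0.42 ± 0.08 (adjusted p = 0.0252 each). Nxpe4 and Kcnj10 rose by 0.94 ± 0.18 and 0.80 ± 0.16. Ifi213 fell by 1.01 ± 0.20 and Dcaf8 by 0.38 ± 0.07. The count of 12, with 8 up and 4 down, came beside 1951 genes at an unadjusted p under 0.05. Of these genes Ifi202b, Gas5, Dcaf8, Fcer1g, Ifi213 and Kcnj10 lie within 10 Mb of Dpt, 6 of 236 against 5 of 22824 elsewhere (odds ratio 119, 95% interval 30 to 501, one-sided Fisher exact p = 4.77e-10). The odds ratio was 24 without the 2 libraries that go against their labels (7 near and 29 elsewhere, 95% interval 8.79 to 56.8) and 40.3 without the 10 libraries. Only Dpt, Ifi202b and Gas5 stayed called whichever library was left out, and Gas5 was 0.17 with its single highest probe set. The count was 100 without the library labelled KO_control 10, 37 without both libraries that go against their labels and 268 with array weights. It was 7 with the single highest probe set, 6 without the 6 Y-expressing libraries and 3 with only the groups compared in the fit. Leaving out each library in turn gave 3 to 100.

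**Figure D5:**
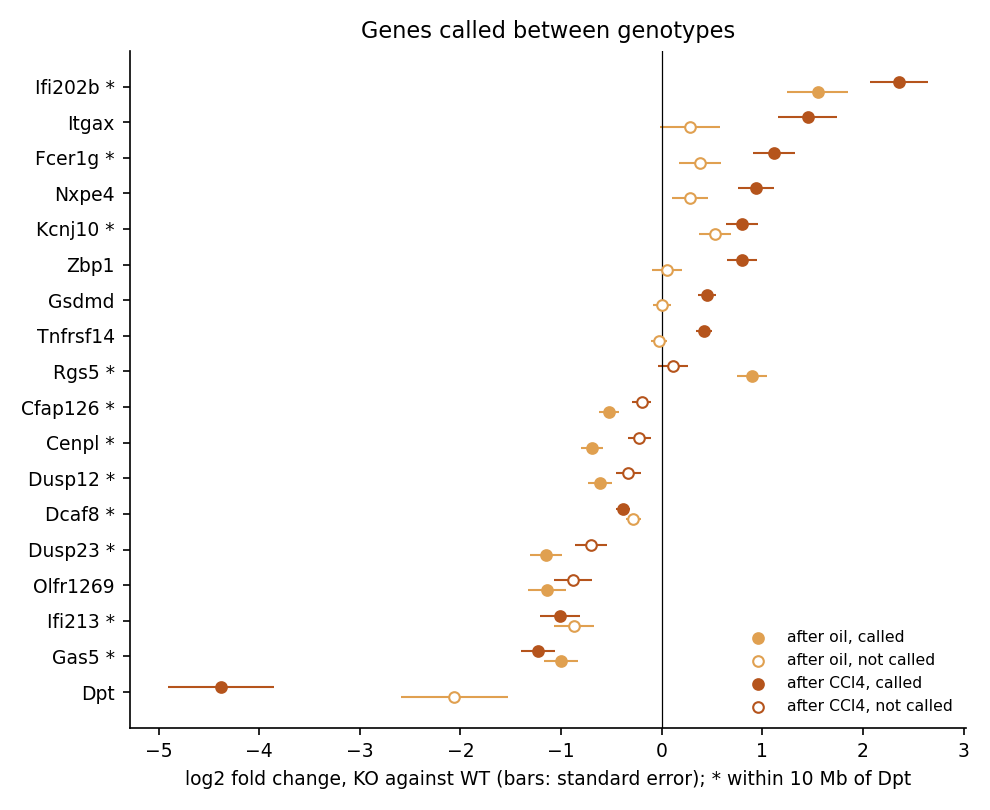
Log2 fold change of KO against WT after oil and after CCl4 for the genes called in either comparison, with standard errors as bars and an asterisk for genes within 10 Mb of Dpt. Ifi202b is at 1.55 after oil and 2.36 after CCl4, and Dpt at -2.06 and -4.38.

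Macrophage markers lay higher in KO after CCl4. Itgax was the 1 called gene of 21, and 15 rose when adjusted over the list alone (median 0.67, camera adjusted p = 1.46e-19, adjusted p = 0.106 with an estimated correlation). The score was higher by 0.67 in KO, in 8 of 9 libraries, but did not pass after adjustment (exact permutation p = 0.00374, adjusted p = 0.0513). Without the 2 libraries with low hepatocyte genes, 1 of several choices made after seeing the data, it was 0.65 and passed (exact permutation adjusted p = 0.0448). The permutation results of this score under the other choices are not given here. WT_CCl4 1, whose Dpt goes against its label, had the lowest macrophage score of its group, 5.99 against a group mean of 6.70. Without the 10 libraries the list median was 0.57, in a fit that keeps WT_CCl4 4, 5, 8 and 9 with their markers of other tissues. Neutrophil markers were higher by 0.53 in 9 of 9 libraries (0 called, 8 adjusted over the list alone, camera adjusted p = 3.03e-11, adjusted p = 0.0707 with an estimated correlation, exact permutation p = 0.0072, adjusted p = 0.0648). Interferon-stimulated genes were higher by 0.35 in 8 of 9 (0 called, 7 adjusted over the list alone, camera adjusted p = 5.93e-14, adjusted p = 0.0564 with an estimated correlation, exact permutation p = 0.00428, adjusted p = 0.0513), with Irf7 at 0.54 ± 0.14 and not called (adjusted p = 0.155). Cell cycle genes lay higher as well (median 0.34, camera adjusted p = 1.19e-09, adjusted p = 0.256 with an estimated correlation), as did acute phase genes (median 0.35, 0.000186, adjusted p = 0.482 with an estimated correlation) and Kupffer cell markers (median 0.34, 0.00727, adjusted p = 0.392 with an estimated correlation). Fatty acid oxidation genes lay lower (median -0.26, camera adjusted p = 8.64e-05, adjusted p = 0.392 with an estimated correlation), with Acadm at -0.31 ± 0.09, and so did oxidative phosphorylation genes (median -0.17, 7.16e-08, adjusted p = 0.282 with an estimated correlation), but these were at -0.02 and not called without the 10 libraries (adjusted p = 0.179). Clock genes were lower by -0.20 in 9 of 9 (camera adjusted p = 0.000805, adjusted p = 0.0363 with an estimated correlation, exact permutation p = 0.00152, adjusted p = 0.0513). Members of this list moved in opposite directions with CCl4, so a lower mean does not describe the clock as a whole.

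None of the 28 matrix genes was called between genotypes after CCl4 (0 by limma, 0 adjusted over the list alone), with Fn1 at 0.24 ± 0.09 (adjusted p = 0.397) and Lum at 0.57 ± 0.27 (adjusted p = 0.575). The matrix score was higher by 0.30 in KO, in 7 of 9 libraries, a difference within the SD of 0.40 in WT and 0.44 in KO (exact permutation p = 0.155, adjusted p = 0.465). By camera the list lay higher (median 0.28, adjusted p = 8.52e-08, adjusted p = 0.392 with an estimated correlation). The library labelled KO_CCl4 5 had the highest matrix score, 7.86 against 6.41 to 6.83 in the rest of its group, and carried adipocyte markers. Without it the score differed by 0.17 (exact permutation p = 0.314). WT_CCl4 3 had the highest matrix score of its own group, 7.07, and carried muscle markers. Without WT_CCl4 3 alone the score differed by 0.38 (exact permutation p = 0.0386, not adjusted over the lists). Binding partners were higher by 0.30 (exact permutation p = 0.0364, adjusted p = 0.164, 8 of 9) and crosslinking genes by 0.26 (exact permutation p = 0.0329, adjusted p = 0.164, 8 of 9), with Tgfb1 at 0.55 ± 0.19 and Plod1 at 0.41 ± 0.12, neither called. By camera these lists gave 0.00132 and 2.79e-05, proteases 6.23e-05 and TGF-beta genes 0.015, and with an estimated correlation adjusted p = 0.392, 0.286, 0.392 and 0.528. Without the 10 libraries the medians went from 0.28 to 0.16 for matrix, from 0.38 to 0.16 for proteases, from 0.27 to 0.12 for crosslinking and from 0.12 to 0.05 for TGF-beta genes, which were no longer called (adjusted p = 0.0658). With the preset correlation camera then called stellate markers higher (median 0.13, adjusted p = 0.0395) and unfolded protein genes lower (median -0.11, 0.00756). These 2 calls rest on that fit, which was chosen after seeing the data. With all libraries stellate markers were not called (camera adjusted p = 0.259, and 0.794 with an estimated correlation). Pancreatic and muscle markers were lower in KO by -1.39 and -1.60 (exact permutation adjusted p = 0.164 each, 9 of 9), and 5 of the 9 WT libraries carry markers of other tissues. Without all 7 such libraries the matrix score was higher by 0.39 in KO (8 against 4, exact permutation p = 0.0242, adjusted p = 0.105), and 103 genes were called. With WT_CCl4 1 left out as well the score differed by 0.17 (8 against 3, exact permutation p = 0.145, adjusted p = 0.395), and 9 genes were called.

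The interaction asked whether the CCl4 effect itself differs between genotypes. No gene was called by limma (0 of 23152), and 1356 had an unadjusted p under 0.05. The CCl4 effect on the macrophage genes Itgax and C1qc differed by 1.17 ± 0.42 and 0.61 ± 0.23, and that on the acute phase gene Saa2 by 2.98 ± 1.02, each with an adjusted p = 0.848. By camera, interferon-stimulated genes had higher CCl4 effects in KO (median 0.35, adjusted p = 6.79e-09, adjusted p = 0.262 with an estimated correlation), as did macrophage markers (median 0.45, adjusted p = 1.69e-06, adjusted p = 0.772 with an estimated correlation) and neutrophil markers (median 0.40, adjusted p = 0.000189, adjusted p = 0.62 with an estimated correlation). Cell cycle (median 0.24, 0.0014) and acute phase genes (median 0.35, 0.00861) also had higher CCl4 effects in KO, while fatty acid oxidation genes (median -0.23, 0.00268), p53 targets (median -0.11, 0.0239) and clock genes (median -0.23, 0.0325) had lower ones. None of these 5 passed with an estimated correlation (adjusted p = 0.951, 0.951, 0.951, 0.681 and 0.262), and clock genes did not pass without the 10 libraries (adjusted p = 0.0704). Pancreatic and muscle markers differed by medians of -1.34 and -1.70 (2.23e-07 each, adjusted p = 0.62 and 0.519 with an estimated correlation). The matrix list did not pass (median 0.19, adjusted p = 0.0963). Without the 10 libraries it passed with the preset correlation (median 0.20, adjusted p = 0.00248), as did Kupffer cell (0.000507), cholesterol synthesis (0.0047), crosslinking (0.0226), mesothelial (0.0296) and binding partner lists (0.0307), while the matrix score did not (0.16, permutation p = 0.12, adjusted p = 0.323). Interaction scores did not pass either, with interferon-stimulated genes at 0.36 (permutation p = 0.0184, adjusted p = 0.359). Differences of genotype after oil and after CCl4 correlated weakly across genes (r = 0.111, jackknife SE 0.213, 2 genes called in both).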

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

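The tests of the WT share of the library labelled KO_control 10 and of positions on the CCl4 axis were chosen only after the result was seen, as were the fits without libraries picked from the data and the use of the Fisher test near Dpt, itself fixed beforehand, to weigh explanations. The genotype of each library is its label, and no direction below was drawn from a relabelled library.

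Dpt and 7 list scores were examined in each of the 4 groups, 32 groups of values in all, and in 17 of them 1 library lay far from the rest. Chance gives about 1 such library in 20 groups. In the library labelled KO_control 10, Dpt was 7.40 (others 3.07 to 3.87), the matrix score 6.90 (4.93 to 5.36), the macrophage score 7.57 (5.27 to 5.57), the pericentral score 6.67 (8.14 to 8.74) and the periportal score 8.53 (8.90 to 9.22). Its scores for other tissues were 4.97 for adipocyte (4.22 to 4.45), 4.47 for pancreatic (3.51 to 3.79) and 6.13 for muscle markers (3.53 to 3.89). In the library labelled KO_CCl4 5, the matrix score was 7.86 (6.41 to 6.83), the pericentral score 5.28 (6.66 to 7.59), the periportal score 5.78 (8.24 to 8.84), the adipocyte score 8.53 (4.38 to 4.90) and the muscle score 3.94 (3.56 to 3.69). In WT after CCl4, Dpt was 3.18 in the library labelled 1 (7.48 to 10.12), the periportal score 5.97 in the library labelled 3 (8.02 to 8.86) and the pancreatic score 10.83 in the library labelled 4 (3.29 to 6.61). In WT after oil the muscle score was 4.18 in the library labelled 2 (3.53 to 3.82).

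The first pattern is the pair of libraries whose Dpt goes against their label. For KO_control 10, 11 genes near Dpt placed it at 0.78 between WT (0) and KO (1), above the other 16 WT libraries (-0.20 to 0.61) and within the other 18 KO libraries (0.46 to 1.47), which argues against RNA of a WT animal alone. RNA with both Dpt alleles may explain it: the fitted WT share was 0.3, below the other 8 WT libraries after CCl4 (0.95 to 1.00) with Dpt above every other KO library, although KO libraries after CCl4 span 0 to 0.54. Across 4272 genes of the CCl4 response it lay at 1.11, among the other CCl4 libraries (0.72 to 1.66) and away from the other oil libraries (-0.06 to 0.07), which is consistent with a CCl4-treated animal. For WT_CCl4 1, the genes near Dpt gave 0.91, as RNA of a KO animal would. Its CCl4 position of 0.21 lay above every other oil library, by little more than their range, and below every other CCl4 library. This cannot decide on an oil-treated animal, since the limit was set after the result was seen and was passed narrowly. A plain exchange of these 2 libraries would put RNA of a WT animal alone in KO_control 10, which its position of 0.78 argues against. A wrong label or a mixed sample stays open for both, and no biological explanation was tested.

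The second pattern is the transcripts of other tissues after CCl4. Second lists, written for the purpose, stood above the median of the other arrays by 7.79 for pancreas in WT_CCl4 4 (11 of 11 genes over 1 log2, libraries without such markers -0.18 to 0.25), by 5.6 for muscle in WT_CCl4 3 (12 of 12, -0.20 to 0.26) and by 3.38 for fat in KO_CCl4 5 (7 of 9, -0.23 to 0.08). These are consistent with pieces of pancreas, muscle and fat, or their RNA, in the respective samples. No biological explanation was tested. In KO_CCl4 5 the high matrix score of 7.86 comes with these fat markers, so that score cannot be read as liver matrix alone. The same holds for the matrix score of 7.07 in WT_CCl4 3, which comes with muscle markers.

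The third pattern is that genes called between genotypes lie near Dpt. An effect of lost Dpt on genes anywhere in the genome does not predict this, and the odds ratio of 709 after oil argues against it as the sole cause. The median share of probe sets with the sign of their gene was 0.923. This cannot decide on a difference under a few probe sets, since the sign comes from the mean of those probe sets. Medians over probe sets were large in some genes, such as Dusp23 (-1.30) and Rgs5 (0.94) after oil. They were small in Gas5 (-0.38 after oil, -0.64 after CCl4) and in Dcaf8 after CCl4 (-0.19). Single Gas5 probe sets reached -5.43 after oil and -5.50 after CCl4. DNA of another strain that flanks the targeted gene and regulation of neighbouring genes by the targeted locus both predict the pattern. They cannot be told apart, because the larger Fisher exact p of both treatments, 4.77e-10 within 10 Mb, only restates it, and within 5 Mb it was 0.0412 after CCl4, or 0.129 without the 2 libraries of the first pattern.

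Whether chance division of the same libraries gives as many called genes was asked with 100 splits per comparison, the real one included. Chance can be excluded for CCl4 in WT (5666 genes, 1 split as large, highest other split 1548), where 7 of the 9 CCl4 libraries were together in that other split. It can be excluded for CCl4 in KO (5389 genes, 1 split as large, highest other 1). Between genotypes, 2 splits were as large after oil (8 genes, highest other 91) and 2 after CCl4 (12 genes, Dpt among them, highest other 31). Both shares met the limit set beforehand for an argument against chance. A random split still gave more genes than the real one in each, so chance is not excluded for these counts. The oil split with 91 genes has all 6 Y-expressing libraries in 1 group, which points to a structure of the samples. For the interaction 0 genes were called, so all 100 splits are as large by construction (highest other 1), and nothing follows about chance.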

How the results depend on the processing

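The fits that leave out libraries picked from the data, or that add Y-linked expression as a term, were chosen after seeing the data, and their tests only after the result was seen, as was the permutation of numbers below. Of 278 called results for named genes, 278 kept direction and call with array weights, with centred arrays and without the 2 libraries whose Dpt goes against their label, 274 with cyclic loess, 258 with Y-linked expression as a term, 220 without the 6 Y-expressing libraries, 255 without the 7 libraries with other tissue markers, 260 without these and the 2 libraries together (8 libraries) and 211 with the single highest probe set. Where not stated otherwise, the cause of a change was not tested. Surrogate variables from sva, a level filter set by negative control probe sets, and the other deposited table were not run. Signal close to background limits what the arrays can show for weakly expressed genes.

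Counts of called genes moved as follows. With the single highest probe set, 5 genes were called between genotypes after oil and 7 after CCl4. With genes at or above the median level only, where fewer genes were tested, 5 were called after oil. Centred arrays gave 21 and array weights 268 after CCl4. A fold of at least 1.5 as a further condition left 2144 for CCl4 in WT and 2268 in KO by its construction. Fits of only the groups compared, with fewer samples, gave 3 after CCl4. Without genes within 10 Mb of Dpt, 1 remained after oil and 5 after CCl4. Without the 2 libraries whose Dpt goes against their label, 37 genes were called after CCl4 and 1 in the interaction. Without the 6 Y-expressing libraries, 3403 were called for CCl4 in WT, 1 for genotype after oil and 6 after CCl4. Without the 7 libraries with other tissue markers, 3391 were called for CCl4 in WT and 103 for genotype after CCl4. Without the 8 libraries, 14 were called for genotype after oil, 9 after CCl4 and 1 in the interaction. Leaving out 10 libraries together gave 36 after CCl4 and 1 in the interaction.

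Dpt after oil, not called in the fit of all libraries, was called at -2.29 with array weights (adjusted p = 0.000466), at -2.45 without the 2 libraries (9.27e-09), at -2.45 without other tissue markers (0.00202), at -2.45 without the 8 libraries (3.44e-14) and at -2.40 without 10 libraries (1.09e-08), while its other alternatives ranged up to an adjusted p = 1.0. The matrix score after CCl4 passed an unadjusted exact permutation test at 0.39 without other tissue markers (p = 0.0242, range over alternatives 0.0242 to 0.318), where WT_CCl4 1 is 1 of 4 WT libraries. Without the 8 libraries it was 0.17 (exact permutation p = 0.145). The correlation of CCl4 effects across genes was 0.908 over genes at or above the median level and 0.73 by Spearman.

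With an estimated correlation, camera called 1 list for CCl4 in WT (27 with the preset correlation), 9 in KO (27), 0 for genotype after oil (9), 1 after CCl4 (16) and 0 for the interaction (10). After oil, 2 lists were called with the single highest probe set, 1 without the 2 libraries, 1 without other tissue markers, 1 without the 8 libraries and 3 without 10 libraries. Without other tissue markers 25 lists were called after CCl4 and 21 in the interaction, and without the 8 libraries 16 in the interaction. List directions between genotypes after oil reversed in 4 settings. Without the 2 libraries, adjusted p was 0.98 for matrix, crosslinking and macrophage lists. Without other tissue markers it was 0.889 for matrix, 0.984 for binding partners and macrophages and 0.944 for proteases. Without the 8 libraries it was 0.908 for matrix, 0.934 for binding partners, crosslinking and macrophages and 0.929 for proteases. Without 10 libraries it was 0.928 for matrix, stellate and macrophage lists and 0.945 for binding partners, crosslinking and proteases. Without other tissue markers these also reversed: muscle markers for CCl4 in WT (0.162) and in the interaction (0.571), B and plasma cell markers for genotype after CCl4 (0.00311), and stellate (0.00746) and T and NK cell markers (0.0375) in the interaction. Without the 8 libraries muscle markers were 0.324 for CCl4 in WT and 0.671 in the interaction, B and plasma cell markers 0.0114 and T and NK cell markers 0.00587.

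With the single highest probe set the sign reversed for Mmp12 (-0.06), Ltbp2 (-0.22), Tgfb3 (-0.12), Tpm2 (-0.10), Cxcr2 (-0.04) and Wt1 (-0.59) with CCl4 in WT, for Tgfb3 (-0.09), Phlda3 (-0.15) and Lrrn4 (-0.03) in KO, and for Gas5 between genotypes (0.01 after oil, 0.17 after CCl4). Myh1 in WT was -0.07 without other tissue markers and -0.08 without the 8 libraries.

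With the number in the title as a block, 133 genes were called between genotypes after CCl4 and 1 list after oil. The median correlation was 0.012 over 51 pairs of libraries with the same number and 0.012 over 434 other pairs, and 4 of 36 libraries correlated best with their own number. A correlation over 0.1 was found in 14 of the 51 and 69 of the 434 pairs. With numbers permuted within groups, p was 0.0188 for that share and 0.0912 for the mean correlation (permutation, one-sided). The labels name no pairing and most pairs are not alike, so the numbers were not taken as pairs, but some likeness is not excluded.

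Leaving out each library in turn gave 4755 to 6378 genes for CCl4 in WT, 4728 to 6479 in KO, 5 to 9 for genotype after oil, 3 to 100 after CCl4 and 0 to 0 in the interaction. After oil, 5 were called without WT_control 2, 4 or 8. After CCl4, the count was 100 without KO_control 10, 86 without KO_CCl4 9, 32 without KO_CCl4 8 and 30 without WT_CCl4 3. It was 7 without KO_CCl4 6, 6 without KO_CCl4 1 or 7, 4 without WT_CCl4 6 or 8, and 3 without WT_CCl4 7 or 9 or KO_CCl4 3 or 4. Dpt ranged from -2.45 to -1.97 after oil, called without KO_control 10 (-2.45) and without WT_CCl4 1 (-2.06), and from -4.97 to -4.10 after CCl4. The matrix score ranged from 0.17 to 0.38, and passed without WT_CCl4 3 (0.38, exact permutation p = 0.0386, highest p = 0.318). Of the named called genes, 117 of 132 for CCl4 in WT, 119 of 127 in KO, 5 of 8 for genotype after oil and 3 of 12 after CCl4 were called in every such fit. Those that were not after oil are Ifi202b, Dusp12 and Cfap126.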

Other observations

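All tests in this part were chosen only after the result was seen.

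Macrophage genes were examined between genotypes in a fit without 10 libraries, namely the 2 whose Dpt goes against their label, the 2 with low hepatocyte genes and the 6 that express Y-linked genes. It kept WT_CCl4 4, 5, 8 and 9, which carry markers of other tissues, while no KO library it kept after CCl4 carries them. Part of its differences between genotypes may come from that imbalance. In this fit 36 genes were called after CCl4 (25 up, 11 down), and 11 of the 12 genes called with all libraries were among them. Among the 25 higher in KO were the phagocyte genes Fcgr1 by 0.86 ± 0.17 (adjusted p = 0.0302), Folr2 by 0.87 ± 0.16 (adjusted p = 0.0151), Ifi30 by 0.85 ± 0.15 (adjusted p = 0.00592), Cyth4 by 0.99 ± 0.20 (adjusted p = 0.0286) and Pirb by 0.81 ± 0.16 (adjusted p = 0.0286), with 8 KO and 7 WT libraries. With all libraries these genes were not called, Folr2 standing at 0.78 ± 0.18 (adjusted p = 0.0734) and Fcgr1 at 0.99 ± 0.21 (adjusted p = 0.0586). The phagocyte genes were chosen after their values were seen, and the 25 also include other genes such as Cdk20, Loxl4 and Kcnj10. Fewer genes were called after CCl4 without the 8 libraries, a fit that also leaves fewer WT libraries. The antithrombin gene Serpinc1 and the pentraxin gene Apcs, both within 10 Mb of Dpt, were called as well, at -0.55 ± 0.09 and 1.13 ± 0.19.

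Genes with sex-biased expression in liver were scored as the mean of 14 male-biased minus the mean of 13 female-biased genes. The 6 oil libraries that express Y-linked genes lay at 4.85 to 5.88, the other 12 oil libraries at -2.21 to 1.41 and the 18 CCl4 libraries at -1.74 to 0.30.

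Differences of genotype after oil and after CCl4 had a correlation across genes of -0.065 in the fit without 10 libraries, against 0.111 with all libraries.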
